A study of Mus musculus with 4 samples.

How the data were processed

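Pol II occupancy was measured by ChIP-seq, in which chromatin crosslinked to a protein is recovered with an antibody and sequenced, in primary mouse osteoblasts. Per the labels, the cells were bone-derived mesenchymal stem cells kept in osteogenic medium, and the antibody recognised RNA polymerase II (Pol II). OSS_128167 is an inhibitor of SIRT6, an NAD-dependent deacylase of chromatin. The 4 samples comprised 1 Pol II library and 1 input library without OSS_128167, and 1 of each with it. Groups were taken from the sample titles. The treatment field of the labels names OSS_128167 for all 4 samples, so untreated here means that the title names no treatment. The untreated titles name WT osteoblasts, while the titles of the OSS_128167 samples name treated osteoblasts without WT. The name of the list deposited for the OSS_128167 library mentions SIRT6 and not the inhibitor. The peak lists of the 2 Pol II libraries were analysed, and the 2 inputs were not analysed here as samples of their own.

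Reads were processed with fastp and BWA against mm10, per the submitters' processing notes. The peak caller, its thresholds and the way in which the inputs entered the calls are not given in the sources used here. Each deposited list has 1 row per peak with a position counted from 1, a length, a fold enrichment (a ratio), a p-value, an FDR and a pileup. The fold enrichment, p-value and FDR of each peak are the authors' values within their own list, and they were used to describe, rank or filter peaks of that list and not to compare peaks between lists. The deposited pileup is a height of signal, in whole units in the OSS_128167 list and in multiples of 0.543 in the untreated list. The lists were made per library and give no position of the highest point of a peak. The largest peak p-value was 0.00956 in the untreated list and 0.00999 in the OSS_128167 list, so the lists are permissive, and a listed peak need not pass a correction for multiple tests. The lists hold no read totals, so the sequencing depth of each library is unknown.

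Genes came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 49943 genes on assembled chromosomes, of which 21887 were protein-coding. That table gives gene boundaries without strand, exons or transcript starts, and no genome sequence was used here. The planned classes of promoter, 3′ end, exon and intron were therefore replaced. A gene-end peak was one whose interval reached within 1000 bp of either boundary of a gene. Peaks were classed as at a protein-coding gene end, inside a protein-coding gene, within 1 kb of another annotated gene, or none of these. Peak summits had been planned as the position of a peak. The whole interval was used in their place after the columns and widths of the peaks had been seen, and before any value of a gene was computed. The peak centre, which is the nearer stand-in for a summit, was run as the alternative and gave 83 genes in the untreated list, 2681 in the OSS_128167 list and 20 in both. Random gene lists were not matched on promoter GC content, and the filter on repeat-rich peaks was not run.

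With 1 library per condition there was no replicate, so the conditions were not tested against each other and no p-value between them is given. Exact (Clopper-Pearson) 95% intervals cover the counting of peaks or genes only, and neither neighbouring peaks nor neighbouring genes are independent. Overlap required at least 1 bp (bedtools 2.31.1). Chance levels came from 100 seeded shuffles of the same intervals within their chromosomes. Shared genes were set beside the product of both counts divided by the 21887 genes. For 27 gene lists holding 536 distinct genes, the number of members with a gene-end peak was ranked among 10000 random lists of the same size from protein-coding genes, or from long non-coding RNA genes for that list. These percentiles describe 1 library each. The histone list was set by a symbol pattern, which also took a few histone genes outside the replication-dependent class, such as H1f0. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9. On simulated data, the interval counts recovered 50 of 50 planted gene-end peaks and differed 0 times from a direct search over 300 genes.

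The gene lists, the main comparisons and most alternatives were fixed before the data were examined. The tests of explanations among the flagged results were chosen after the results were seen, except that the bounds for shallow input scaling were written before its result. An FDR of at most 0.05, the removal of dense 1 Mb bins, the background implied by fold and pileup, the relations across chromosomes and the ranking of long genes were added after the data were seen. Genes were named by a rule fixed with the gene lists. It took the 10 protein-coding genes with the highest gene-end fold in each list, up to 4 members per gene list and library (up to 6 in the untreated list), and the 10 genes of highest fold with a gene-end peak in the untreated list alone. It also took the 3 peaks of highest fold per list, and Sirt6, Col1a1, Col1a2, Runx2, Alpl, Bglap, Cd47, Calr, Actb and Gapdh. Of the genes it allows, those in the text are a selection made after their values were seen. Alternatives were FDR limits of 0.05 and 1e-05, a fold of at least 5, equal list lengths, assembled chromosomes alone, other definitions of overlap, windows of 500 and 2500 bp, peak centres, all genes, and gene length minimums of 2 and 20 kb.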

Results

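Pol II peaks were listed in primary mouse osteoblasts cultured without OSS_128167 and with it, from 1 ChIP-seq library per condition. The design asks where Pol II lay on the genome in the absence and presence of this SIRT6 inhibitor. The untreated group rests on the sample titles alone, because the treatment field of the labels names OSS_128167 for all 4 samples. There was no replicate in either condition, so differences between the lists compare 2 libraries and not the treatment. Positions are on mm10, and each fold is the authors' enrichment of that peak within its own list.

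The OSS_128167 list was led by histone genes and small nuclear RNA genes, and the untreated list by peaks outside the gene lists examined. In the OSS_128167 list the highest fold was 22.8, in a peak of 4628 bp on chromosome 3 from 96245966 to 96250593 over H2ac18 and H3c14, which encode core histones. The next were 22.2 at Rnu5g, a U5 small nuclear RNA gene, and 20.7 at H3f3b, which encodes the replacement histone H3.3. In the untreated list the highest fold was 8.84, on chromosome 18 from 4197178 to 4197599 at the pseudogene Gm10557. It was followed by 8.83 on chromosome 4 inside Zfp600 and the pseudogene Vmn2r-ps17, which overlap, and by 8.22 on chromosome 3 from 142191647 to 142191868, with no annotated gene within 1 kb.

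The untreated list held 1694 peaks covering 0.484 Mb and the OSS_128167 list 40748 peaks covering 14.1 Mb. Median peak lengths were 251 and 278 bp, and the longest peaks 1381 and 29800 bp. Most of the untreated peaks had no support after correction for multiple tests, since 1378 (81.3%) had an FDR of 1 and 109 had an FDR of at most 0.05. In the OSS_128167 list 6568 peaks (16.1%) had an FDR of at most 0.05. At an FDR of at most 1e-05 the lists held 23 and 425 peaks.

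**Figure D1:**
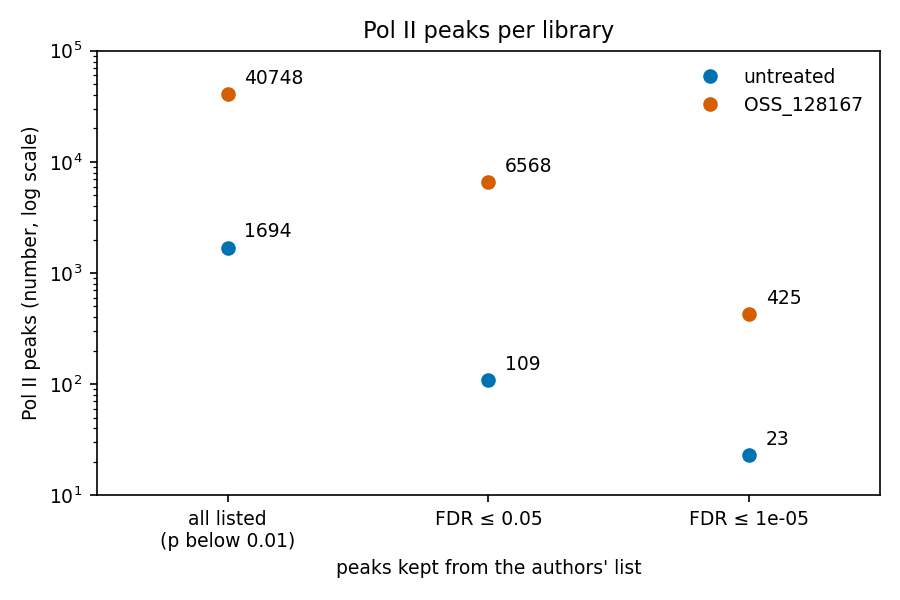
Number of Pol II peaks (log scale) in the untreated and the OSS_128167 list, for all listed peaks and at 2 FDR limits, with 1 library per condition. The OSS_128167 list is longer at each limit, with 40748 against 1694 peaks in full and 425 against 23 at an FDR of at most 1e-05.

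Few positions were shared, and those at genes included Col1a2, Ccn1, Ier2 and histone genes. On assembled chromosomes 99 of 1616 untreated peaks (6.13%, exact 95% interval 5.01 to 7.41) overlapped an OSS_128167 peak, where shuffled untreated peaks gave a mean of 17.4. In the other direction 84 of 40666 OSS_128167 peaks (0.207%, 0.165 to 0.256) overlapped an untreated peak, against a mean of 17.5. Between peaks with an FDR of at most 0.05, 3 of 102 untreated peaks overlapped the OSS_128167 list.

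Gene ends carried more peaks than shuffled positions in both lists. Of the OSS_128167 peaks 3448 (8.48%, 8.21 to 8.75) lay at an end of a protein-coding gene, against 3.60% for shuffled peaks. Of the untreated peaks 88 (5.45%, 4.39 to 6.67) did, against 3.51%. At an FDR of at most 0.05 the shares were 17.5% (16.6 to 18.4) for OSS_128167 and 13.7% (7.71 to 22.0) for untreated peaks. Shuffled peaks gave 3.92% and 3.57% at this limit. The untreated share rested on 14 of 102 peaks. Genes behind it included Speer4e, Gm21083, Speer4d, Gm21190, 4930467E23Rik, 9530057J20Rik and Gm21119, which lie in the dense bins described below. The untreated share at this limit was not recomputed without those bins. In the full lists the interior of protein-coding genes held 40.2% of OSS_128167 and 39.0% of untreated peaks, near the 38.4% and 39.4% of shuffled peaks.

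Protein-coding genes with a gene-end peak numbered 86 in the untreated list and 3094 in the OSS_128167 list, where shuffled peaks gave means of 61.4 and 1532. Both lists held 27 of them, against 12.2 for independent lists. These included Col1a2, Ccn1, Ier2, H3c13, H2bc18, H4c4 and Eapp, although both peaks at Eapp lay outside it and over the small nuclear RNA gene Gm22513. Also among them were Gm10354, Gm21190, Speer4d and Gm15319, which lie in the dense 1 Mb bins described below. A shared gene need not hold overlapping peaks, since at several of the 27 the gene-end peaks of the lists lay apart, such as Enpp4, Zfp39, Ptcd3, Zfp938, Tgtp2 and Gm15319. The 27 therefore do not count shared positions. At an FDR of at most 0.05 the counts were 13, 1143 and 1, with 0.679 shared genes for independent lists. The shared gene was Speer4d, in a cluster of near-identical genes. The untreated genes of highest fold were Slc30a4 (8.03), a zinc transporter, 4930467E23Rik (6.75), Speer4e (6.35), 9530057J20Rik (5.40), Gm4340 (5.39) and Vmn1r166 (5.34), a vomeronasal receptor. None of these had a gene-end peak in the OSS_128167 list, but that list had 2 peaks inside 4930467E23Rik and 3 inside 9530057J20Rik. Both of these genes and Speer4e lie in those dense bins.

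Col1a1, Col1a2 and Fn1 were covered by Pol II peaks over most of their length in the OSS_128167 list, unlike most matrix genes. Of the 26 extracellular matrix genes 5 were covered over at least 50%, and the median was 5.07%. Col1a1 and Col1a2 encode the chains of type I collagen, the main protein of bone. Col1a2 (chromosome 6, 4505618 to 4541543) was covered over 97.4% of its length, with a peak of 29800 bp, a fold of 9.03 and an FDR of 8.15e-26. Col1a1 (chromosome 11, 94936224 to 94953042) was covered over 98.2%, with a peak of 16389 bp, a fold of 9.42 and an FDR of 1.56e-29. In the untreated list Col1a2 was covered over 8.5% (gene-end fold 3.77, FDR 1) and Col1a1 had no peak. Fn1, which encodes fibronectin, was covered over 64.8% in the OSS_128167 list, and its 1 untreated peak had an FDR of 1.

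**Figure D2:**
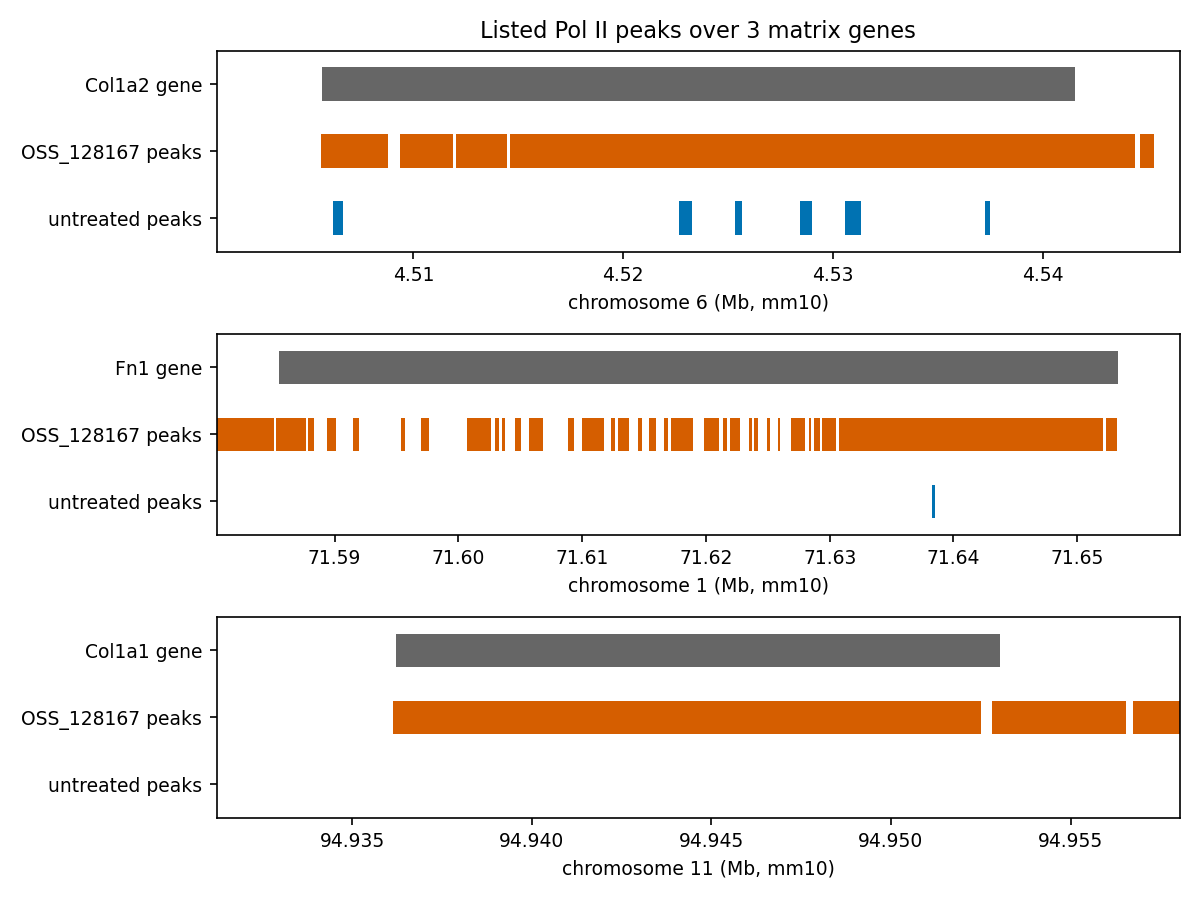
Listed Pol II peaks over Col1a2, Fn1 and Col1a1 (position in Mb on mm10, genes as grey bars, peaks of each list as coloured bars, 1 library per condition). OSS_128167 peaks cover 97.4%, 64.8% and 98.2% of the 3 genes, while the untreated list has short peaks over Col1a2, 1 over Fn1 and none over Col1a1.

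In the OSS_128167 list 20 of 26 extracellular matrix genes had a gene-end peak (76.9%, 56.4 to 91.0), against 14.1% of protein-coding genes, and the count exceeded those of all 10000 random lists. The count was 13 at an FDR of at most 0.05 (50%, 29.9 to 70.1), against 5.22%. Sparc, a collagen-binding matrix protein, had a fold of 7.77, Postn 5.95 and Thbs1 4.78. Of 25 osteoblast genes 7 had one, at the 94.7th percentile of random lists, and 6 at an FDR of at most 0.05, at the 99.8th. They included Runx2, the transcription factor required for osteoblast formation (fold 3.27, FDR 0.00173), with 63 peaks over its length. Alpl and Bglap, which encode alkaline phosphatase and osteocalcin, had no peak in either list. The stromal progenitor list had 9 of 20 members (99.9th percentile), among them Vim (6.75) and Cxcl12 (4.41), and 5 at an FDR of at most 0.05 (99.7th). In the untreated list 1 osteoblast gene and 1 matrix gene had a gene-end peak, in both cases Col1a2, and 0 stromal genes.

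Most histone, immediate early, cytoskeletal and ribosomal protein genes had gene-end peaks in the OSS_128167 list. Of 67 histone genes 61 had one (91.0%, 81.5 to 96.6), and 60 at an FDR of at most 0.05. Histone genes lie in clusters and share peaks, and the 60 genes rested on 47 peaks. Of 25 immediate early genes, which respond within minutes to stimuli, 22 had one, including Ccn1 (11.3), Ier2 (9.93), Junb (9.76) and Fos (7.24), and 20 at an FDR of at most 0.05. The cytoskeleton list had 16 of 18, with Actg1 at 11.3 and Actb at 9.71, and the ribosomal protein list 41 of 55, with Rpl3 at 8.32, and at that limit 11 and 32. The untreated list held 3 histone genes (H3c13, H2bc18 and H4c4), 2 immediate early genes (Ccn1, 3.21, and Ier2, 2.60), and 0 cytoskeletal and 0 ribosomal protein genes. Each of these untreated peaks had an FDR of 1.

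Long non-coding RNA genes had 8 of 10 members in the OSS_128167 list, with Neat1 at 8.39 and Snhg1 at 8.30 (7 at an FDR of at most 0.05), and 1 in the untreated list, Snhg1 at 3.10 with an FDR of 1. The heat shock and unfolded protein list had 13 of 20, including Ddit3 (6.76) and Atf4 (4.96), and 4 at an FDR of at most 0.05. Glycolysis had 8 of 19, including Gapdh (6.20) and Ldha (5.29), and 6 at that limit, and proliferation 6 of 17, at the 97.7th percentile in full and the 77.5th at an FDR of at most 0.05. In total 10 of the 27 lists lay in the top 2.5% of random lists in the OSS_128167 list, and 10 at an FDR of at most 0.05. In the untreated list 3 did (histones, immediate early and long non-coding RNA), and 0 at an FDR of at most 0.05. These ranks rested on 3, 2 and 1 genes. The gene-end peak of highest fold was the same for the histone genes H3c13 and H2bc18, so these members were not independent.

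**Figure D3:**
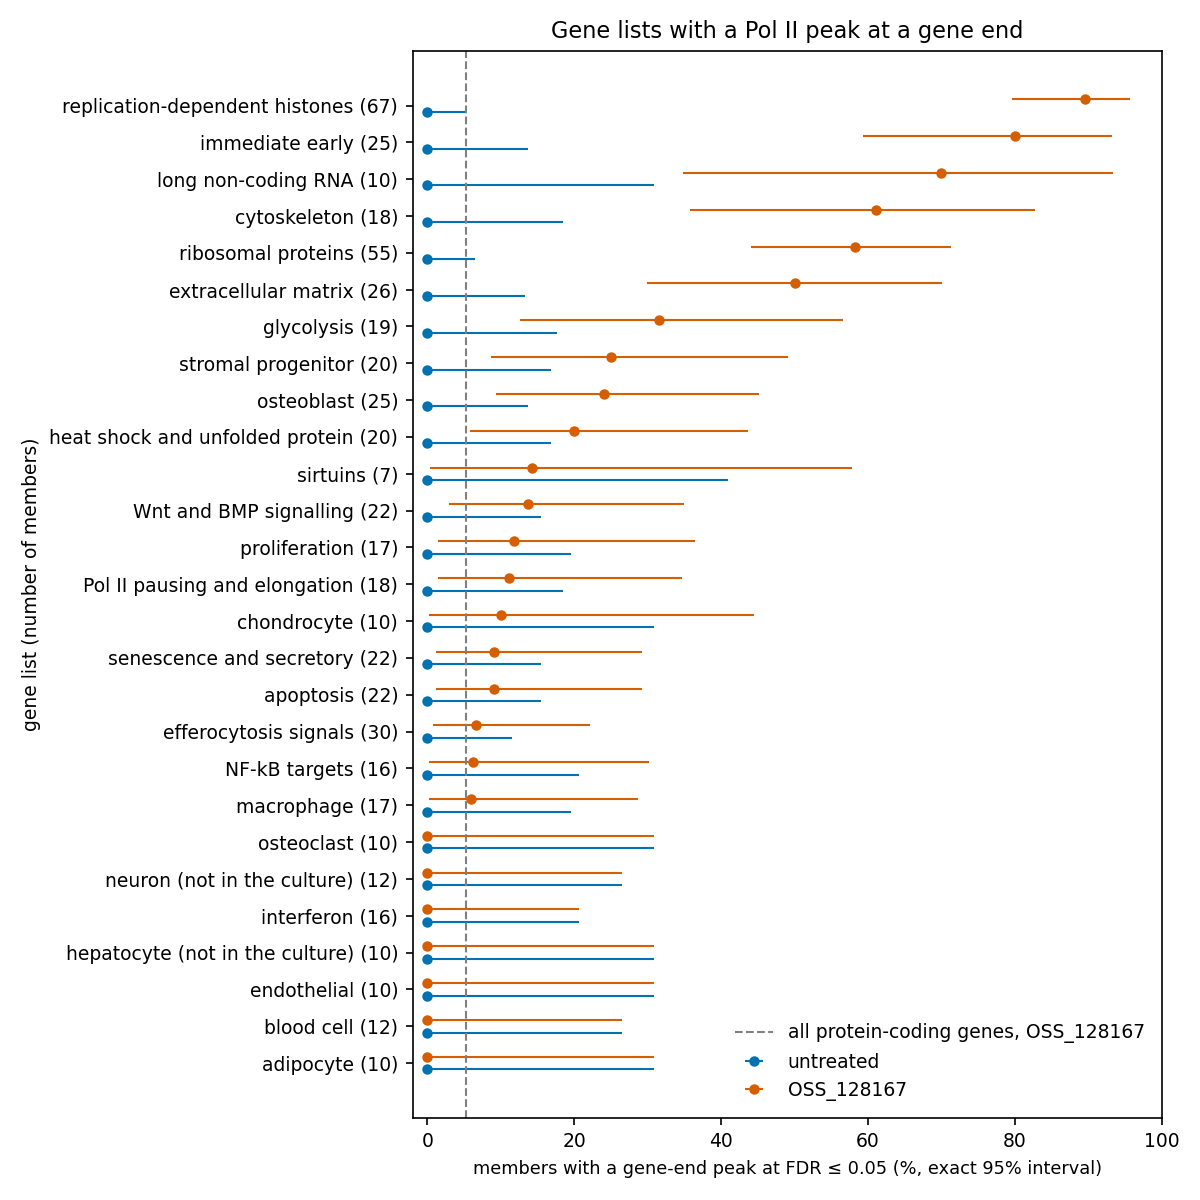
Share of members of each gene list with a gene-end Pol II peak at an FDR of at most 0.05 (percent, points with exact 95% intervals for counting, list size in brackets) in the untreated and the OSS_128167 list, with 1 library per condition. The dashed line marks 5.22%, the share of all protein-coding genes in the OSS_128167 list, and each untreated point lies at 0.

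Genes for the recognition and clearance of dying cells, the subject of the series title, had gene-end peaks about as often as random lists. In the OSS_128167 list 5 of 30 efferocytosis genes had one, at the 58.5th percentile, and 2 at an FDR of at most 0.05, at the 53.3rd. The untreated list had 0. They were Anxa1 (fold 4.64, FDR 3.52e-11), Thbs1, Calr (2.52, FDR 0.0513), which encodes the eat-me signal calreticulin, Lrp1 (2.83, FDR 0.208) and Stab1 (3.01, FDR 0.183). Cd47, which encodes a don't-eat-me signal, had no gene-end peak in either list and 1 interior peak in the OSS_128167 list. Apoptosis genes had 5 of 22 (81.1st percentile), with Mcl1 at 5.12, senescence and secretory genes 4 of 22, with Cdkn1a at 3.86, and NF-kB targets 1 of 16 (Nfkbiz). Wnt and BMP signalling had 4 of 22, with Id3 at 9.34, genes of Pol II pausing and elongation 4 of 18, with Polr2a at 8.53, and interferon genes 1 of 16 (Irf7). These 6 lists had, in this order, 2, 2, 1, 3, 2 and 0 members at an FDR of at most 0.05. The untreated list had 0 members of these lists with a gene-end peak.

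Sirt6, whose product is the target of OSS_128167, had no peak in either list. Of the 7 sirtuin genes Sirt4 alone had a gene-end peak in the OSS_128167 list (fold 13.9), and that peak also lay within 1 kb of the small nuclear RNA genes Gm24265 and Gm24407. Against 14.1% of protein-coding genes, no list of another cell type lay in the top 2.5% of random lists there. Macrophage genes had 1 of 17 (Cd68, 4.39), osteoclast genes 1 of 10 (Siglec15), endothelial genes 2 of 10 (57.3rd percentile), chondrocyte genes 1 of 10 (Sox9, 3.90) and blood cell genes 1 of 12. Adipocyte genes had 0 of 10, and the control lists of neuron and hepatocyte genes 0 of 12 and 0 of 10. Macrophage and chondrocyte genes kept 1 each at an FDR of at most 0.05, and the others 0. The control lists were not free of peaks once interior peaks were counted. Then 6 of 12 neuron and 4 of 10 hepatocyte genes had a peak in the OSS_128167 list, and 2 and 0 at that limit. The untreated list had 0 members of these cell type lists with a gene-end peak.

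In both lists, genes with a gene-end peak had interior peaks more often than genes without one. A long peak that reached both parts was counted for both. Of protein-coding genes of at least 5 kb with a gene-end peak, 1445 of 2452 (58.9%, 57.0 to 60.9) in the OSS_128167 list and 28 of 54 (51.9%, 37.8 to 65.7) in the untreated list also had an interior peak, and these intervals overlap. Without a gene-end peak the shares were 35.6% and 2.46%. Gene length and local clustering of peaks were not held fixed in this comparison. The untreated genes with a gene-end peak included 4930467E23Rik, with 8 peaks in the gene, and Gm21119, with 10, both in the dense 1 Mb bins described below. Among the genes with interior peaks in the OSS_128167 list were Postn, with 16 peaks in the gene, Sparc with 17 and Fn1 with 32. Peaks within 1 kb of both ends were found in 170 of these 2452 genes and in 2 of the 54.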

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

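The bounds for the test of shallow input scaling were written before its result was seen, and the other tests in this part were chosen after the results were seen. Outside the protein-coding comparison, 65 of 1004 small nuclear RNA genes (6.47%, exact 95% interval 5.03 to 8.18) had a gene-end peak in the OSS_128167 list and 3 in the untreated list. As a class they had one less often than protein-coding genes in the OSS_128167 list (14.1%). At an FDR of at most 0.05 the shares in that list were 3.78% and 5.22%. The windows of both ends merge at short genes, which gives a peak less room. Gene length was not held fixed, and no shuffled level was computed for small nuclear RNA genes. In the full untreated list the shares were 0.299% and 0.393%. Rnu1a1, a U1 small nuclear RNA gene chosen after its values were seen, had folds of 19.3 (FDR 1.13e-94) in the OSS_128167 list and 4.85 (FDR 0.0736) in the untreated list. Outside the assembled nuclear chromosomes, where no genes were kept for these counts, the untreated list had 78 peaks and the OSS_128167 list 82.

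Gene-end peaks were far fewer in the untreated list, at genes such as Col1a1, Actb and H3f3b. Under the assumption that fold equals the pileup plus 1 over the background plus 1, the recomputed Poisson p-values lay within 0.00546 log10 units of the deposited ones, and with the shortest peak as fragment length the implied fragment density of the untreated ChIP was 1.11 times that of the OSS_128167 ChIP, which argues against a shallower ChIP. With the enrichment of the OSS_128167 library, scaling to a shallow input would by a Poisson model still have let 422 of the 425 OSS_128167 peaks with an FDR of at most 1e-05 pass, against 24 found, a ratio of 17.6. Among the 100 OSS_128167 peaks of highest fold 16% were found in the untreated list, 32.3 times the share among the other peaks with an FDR of at most 0.05. Peaks of high fold were also long, such as 7528 bp at H3f3b, against a median of 319 bp at that FDR limit. A longer peak is overlapped more easily, and peak length was not held fixed. How much of this ratio comes from the same sites at lower enrichment is therefore unknown. A weaker untreated immunoprecipitation and more Pol II at genes after OSS_128167 cannot be told apart with 1 library per condition.

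Untreated peaks with an FDR of at most 0.05 gathered in 4 bins of 1 Mb, on chromosome 5 from 14 to 16 Mb (Speer genes) and chromosome 8 from 19 to 21 Mb (Defb genes and 4930467E23Rik), which held 66 of 109 (60.6%, 50.7 to 69.8). The OSS_128167 list had 40 peaks with an FDR of at most 0.05 in the same bins, but its peaks overlapped 8 of the 66, so Pol II at genes that differ between the conditions stays open. The median implied background of the untreated peaks was 4.38 times the floor of that list there and 1.26 times elsewhere. Reads shared between near-identical gene copies are a candidate explanation.

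Listed untreated peaks were also dense on whole chromosomes, with 1.22 to 2.08 per Mb on chromosomes 6, 10, 17 and 19 and 0.0333 to 0.902 on the other 16, leaving out the dense bins. Chromosomes 6, 10, 17 and 19 held 277, 265, 116 and 100 untreated peaks, of which 1, 1, 1 and 0 had an FDR of at most 0.05. Almost all peaks behind the density on these chromosomes thus lacked support after correction for multiple tests. Across 20 chromosomes, which are not independent replicates, this density followed the median background implied in the OSS_128167 list (Spearman rho 0.916, permutation p 2e-05, the smallest that these permutations can give, adjusted 6e-05 over 3 relations; Pearson r 0.897, and 0.844 without chromosomes 10 and 19). Within the 16 other chromosomes rho was 0.844 (permutation p 0.00014) and r 0.606 (0.0146), but the untreated list's own median background was at most 1.05 times its floor on chromosomes 6, 10, 17 and 19 and up to 1.76 times on the others outside the dense bins, so extra copies of whole chromosomes stay open as a hypothesis. With genes per Mb rho was 0.477 (permutation p 0.0364, adjusted 0.0385) and r 0.257 (permutation p 0.286). Once the background was held fixed this rho fell to 0.109, against 0.892 for the background with gene density held fixed. Little of the relation with gene density was therefore left beyond the background, although the rho of 0.477 alone does not exclude gene density. With OSS_128167 peaks per Mb, the third relation, rho was 0.468 (permutation p 0.0385), which does not bear on gene density. Col1a2 lies on chromosome 6 and Neat1 on chromosome 19, and no biological explanation by treatment was tested.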

How the results depend on the processing

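The FDR limit of 0.05 was added after the data were seen, and the other settings were planned. With the dense 1 Mb bins left out (also added), on assembled chromosomes alone, with peak centres for gene counts, or with an overlap of 50% of the shorter peak, the counts and shares over whole peak lists that were rerun stayed within 1.5 times their value or within their interval. Without the dense bins the interior shares and the gene lists were not rerun, and the overlap of 50% covered the overlap shares alone. Counts of single gene lists were less stable. With peak centres no OSS_128167 list gained members and many lost some, by over 1.5 times or to 0 in 4 lists (heat shock and unfolded protein 8, efferocytosis 3, apoptosis 3, interferon 0). Over both libraries 14 list counts changed by over 1.5 times, or to or from 0, with a window of 2500 bp (efferocytosis 10 and apoptosis 9 in OSS_128167), 9 with 500 bp (heat shock and unfolded protein 7, glycolysis 4), 16 with equal list lengths (in OSS_128167 heat shock and unfolded protein 3, matrix 9, stromal progenitor 3, efferocytosis 2), 17 at an FDR of at most 0.05 (matrix 13, stromal progenitor 5, efferocytosis 2) and 27 at 1e-05 (matrix 5, stromal progenitor 2, efferocytosis 1). At an FDR of at most 1e-05 the untreated list had 23 peaks, 4.35% overlapped, 8.70% at gene ends, 2 genes (interior peaks in 100% of those of at least 5 kb, which rests on Slc30a4, where 1 peak counted for both parts) and 0 gene lists in the top 2.5% of random lists, and the OSS_128167 list 425 peaks, 48.3% at gene ends, 261 genes and 49.3% with interior peaks, with 0 shared genes. At an FDR of at most 0.05 these were 109, 2.75%, 13.7%, 13, 100% (4 of 4 genes of at least 5 kb, exact interval 39.8 to 100) and 0 for the untreated list, and 6568 peaks, 0.0457% overlapped, 17.5%, 1143 and 42.4% for OSS_128167, with 1 shared gene. With a fold of at least 5 the untreated list had 50 peaks, 0% overlapped, 15.9% at gene ends and 6 genes, and the OSS_128167 list 375 peaks, 0% overlapped, 45.9% and 221 genes, with 0 shared genes. With both lists at 1694 peaks of lowest p, 2.83% of untreated and 1.95% of OSS_128167 peaks overlapped, 30.9% of OSS_128167 peaks lay at gene ends, 565 genes had one, 39.4% of the long ones had interior peaks, and 14 genes were shared. These settings keep fewer peaks by construction. With peak centres within 250 bp, 3.36% of untreated and 0.140% of OSS_128167 peaks overlapped. A window of 500 bp gave untreated values of 3.09% at gene ends, 55 genes and 71.9% with interior peaks, OSS_128167 values of 5.22%, 2053 and 68.7%, and 12 shared genes. A window of 2500 bp gave 12.4%, 171 and 28.8%, then 16.6%, 5343 and 45.8%, and 66 shared genes. Both follow from the width of the window. With all genes the counts were 153, 4645 and 46. With gene length minimums of 20 and 2 kb, 69.6% and 56.8% of OSS_128167 genes had interior peaks, and the cause was not tested. OSS_128167 peaks lay at gene ends more often than untreated peaks under each setting run for both. The filter on repeat-rich peaks and the matching on GC content were not run, as no genome sequence was used here. No paired analysis was possible because each condition had 1 library, which also rules out leaving a library out. Read totals are not given, and the implied ChIP fragment density rests on the assumptions stated with it. An unlisted peak was not called in that library and need not be absent.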

Other observations

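The rankings in this part were chosen after the data were seen, and their genes were named after their values were seen. Among 2429 protein-coding genes of at least 100 kb, the median density in the OSS_128167 list was 11.0 peaks per Mb. Fgfr2, a fibroblast growth factor receptor, was first with 58 peaks (556 per Mb), against 18.2 per Mb for its chromosome 7, and these covered 64.4% of the gene. Cald1, which encodes the actin-binding caldesmon, followed with 87 peaks (492 per Mb), Cdh11, the cadherin known as OB-cadherin, with 47 (306 per Mb) and Gxylt2, a xylosyltransferase, with 24 (226 per Mb). Runx2 ranked 5th with 63 peaks (198 per Mb, against 18.7 for chromosome 17), which covered 8.4% of the gene. The untreated list had 2 peaks in Runx2, 1 in Cdh11 and 0 in Fgfr2, Cald1 and Gxylt2.

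The longest OSS_128167 peaks after those of Col1a2, Fn1 and Col1a1 lay at the long non-coding RNA genes Mir100hg (15066 bp, fold 12.2) and Neat1 (14349 bp), followed by Fgfr2 (12778 bp) and Actb (11859 bp). Chromosomes 13 and X had 5.70 and 3.30 OSS_128167 peaks per Mb, against 14.9 to 19.3 on the other chromosomes from 1 to 19. Nfe2l3 was another shared gene, with folds of 4.03 (FDR 0.850) in the untreated and 8.88 in the OSS_128167 list.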
